A study of Rattus norvegicus with 10 samples.

How the data were processed

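The samples were 5 synovial tissue samples from rats with collagen-induced arthritis and 5 from normal rats, each hybridised as Cy3-labelled cRNA to 1 Arraystar rat circRNA array after RNase R digestion of total RNA, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Per the file headers, the intensity values were extracted with Agilent Feature Extraction 11.0.1.1 in 1 colour, under the same protocol, scanner model and array design for all 10 arrays. The processed intensity is background-subtracted and corrected within the array by that software, per the file headers, with no normalization between arrays. The deposited value table holds log2 values whose scale, centring and direction are not stated; the submitters' processing notes name limma without a version or role. Its columns followed the median spot signal of their own array (Spearman correlation across probes 0.9993 to 0.9999). They lay at a median distance of 0.072 to 0.088 from the quantile-normalized log2 median signal, with column medians of 6.76 to 6.80. The table was therefore read as log2 intensity between arrays with near-common quantiles and without background subtraction; the step that made the remaining difference stays unknown. It served as an alternative only.

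Each array held 15701 spots. The 14145 circRNA probes had 1 spot each, and 536 control spots were left out. A further 62 linear-transcript probes with a transcript accession had 10 spots each, averaged on the log2 scale without spots marked as outliers, and 20 other probes without a name were not used. Gene symbols came from a RefSeq gene table of assembly GRCr8, matched by accession without version, and 39 of the 62 linear probes matched. No column or table used here pairs a circRNA probe with a host gene, class or position. The tests fixed for host gene lists, circRNA classes and circRNAs of 1 host gene could therefore not be run, and the 24 lists were looked up among the linear probes only. No per-sample column was left unmapped.

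The log2 processed signal of each probe was taken relative to the array's 75th percentile over circRNA probes. Probes well above background on at least 5 of the 10 arrays were kept (13945), and 54 of these with a spot marked as an outlier on any array were left out, which left 13891. No circRNA spot was saturated. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over circRNA probes and separately over linear probes, and a two-sided threshold of 0.05. A looser rule, a fold change of at least 1.5 and an unadjusted p under 0.05, was listed beside it. Separation of the groups was tested with a pseudo-F over all kept probes and an exact permutation test over the 126 divisions into 5 and 5. Array measures were compared with two-sided exact permutation tests, adjusted together. A linear probe counted as well above background on an array where at least 50% of its spots were. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

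The tests, the alternatives and the rule for named probes were fixed before the data were examined. The rule took, in each direction, up to 12 probes past the adjusted threshold with non-overlapping groups, filled up to 10 by the smallest unadjusted p, then up to 4 members of each list tested and host genes with at least 3 such probes. Since no probe passed, it gave 10 probes per direction, and because they have no name 2 identifiers per direction are printed. The linear-transcript comparison, its named genes (those past the adjusted threshold, those with a symbol and an unadjusted p under 0.05, and members of the lists) and the comparison within scan run 1 were added after the data were examined. Scan runs were read from the scan times in the file headers, and no array position occurred more than once within a run.

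Alternatives were quantile normalization, median centring, the 75th percentile over probes detected on all arrays, normexp background correction with an offset of 50, the deposited value table, no filter, a filter on all 10 arrays, scan run as a block, the replicate number as a block, a trended and robust variance, array weights, and leaving out each array. Normexp was run on the median spot signal because the mean spot signal was not among the columns used here.

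The procedure was tested on simulated data with the means of the 13891 real probes and 200 probes changed. For 5 against 5 arrays with the spread of these arrays, 12% of 100 probes changed 2-fold and 64% of 100 changed 4-fold were recovered, with 5 false calls among 81. With the spread of the CIA arrays, a simulated shift between scan runs and scan run as a block, 0% of the 2-fold and 23% of the 4-fold changes were recovered, with 4 false calls. Without the block, the same simulation gave 3263 false calls among 3393. Noise was drawn independently for each probe, and the shift between runs came from a standard normal distribution and not from these arrays. The counts of false calls therefore do not carry over to real arrays, whose probes vary together.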

Results

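Circular RNAs (circRNAs), closed transcripts made when a splice donor is joined to an upstream splice acceptor, were measured in the synovium, the tissue that lines the joint. The tissue came from male rats with collagen-induced arthritis (CIA), a model in which immunisation with collagen leads to joint inflammation, and from normal rats. Both groups held 5 samples, each on 1 single-colour array, with rats aged 7 to 8 weeks and samples labelled day 21. RNase R, an exonuclease that degrades linear RNA and spares circles, was applied before labelling. The labels number the samples within a group without saying that each number is a separate animal, so p-values measure the spread between these samples, which may be technical. The arrays were scanned in 2 runs that nearly followed the groups. Scan run 1 held normal replicate 1 and all 5 CIA arrays, and scan run 2 held normal replicates 2 to 5. Normal replicate 1 was thus the only normal array scanned with the CIA arrays, so scan run and group were largely confounded. The number of arrays limits the precision of every value below.

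The 75th percentile of the processed circRNA signal was 199 ± 69.6 units in the normal group and 341 ± 47.6 units in the CIA group (SD, n = 5 each). The two-sided exact permutation p was 0.016, and the difference did not pass after Benjamini-Hochberg adjustment over 5 array measures (adjusted p = 0.079). Normal replicate 1 stood at 315 units and the 4 normal arrays of scan run 2 at 170 ± 29.2 units (SD, n = 4). The share of circRNA probes well above background was 92.8% ± 4.80 in the normal group and 97.8% ± 2.76 in the CIA group (SD, n = 5 each), which did not pass the two-sided exact permutation test either (p = 0.071, adjusted p = 0.087). Of 14145 circRNA probes, 13891 entered the comparisons.

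The first comparison asked which circRNAs differed between arthritic and normal synovium. No circRNA probe passed an adjusted p of 0.05 in limma, the smallest adjusted p being 0.090, while 4498 probes (32.4%) had an unadjusted p under 0.05, against 695 expected by chance. At a fold change of at least 1.5 and an unadjusted p under 0.05, a looser rule, 4404 probes were listed, 2742 higher and 1662 lower in CIA. The 62.3% share of higher probes depended on the processing: it was 48.3% after median centring, 51.9% in the deposited value table and 34.6% after normexp background correction. The median log2 fold change of all probes moved with it, from 0.19 to 0.05, 0.05 and -0.19 in the same order. Each fold change below thus stands against the median probe of its own setting. That median was 0.19 in the main fit, 0.04 with scan run as a block and -0.19 after normexp.

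The probes with the smallest p in each direction are given by identifier because the files pair no circRNA probe with a gene or position, and none of them passed the adjusted test. The 10 that were higher in CIA differed by 2.86-fold to 18.3-fold (adjusted p = 0.090 to 0.096), and in all 10 the CIA arrays lay above every normal array. ASCRPR013337 had a log2 level relative to the array's 75th percentile of -4.43 ± 0.94 in normal and -0.23 ± 1.09 in CIA tissue (SD, n = 5 each), or 18.3-fold (log2 fold change 4.20, SE 0.56). It was well above background on 2 of the 5 normal arrays and on all 5 CIA arrays. The size of the difference depended on the processing: its log2 fold change was 1.86 after normexp background correction and 2.84 in the deposited value table. ASCRPR009899 was 3.83-fold higher in CIA (log2 fold change 1.94, SE 0.30) and was well above background on 3 of the 5 normal arrays; its log2 fold change was 0.14 after normexp (adjusted p = 0.55) and 0.75 in the deposited value table. Over the 10 probes the log2 fold change was -0.21 to 1.86 after normexp. Normexp was run with an offset of 50 added to every signal, which shrinks differences between dim signals. The median of all probes was -0.19 after it. Small values after normexp therefore do not settle the direction of probes near background. The 10 that were lower in CIA differed by 2.31-fold to 4.54-fold (adjusted p = 0.096), and in 9 of them the groups did not overlap. After normexp their log2 fold changes were -1.72 to -0.97. ASCRPR002331 had a log2 level of -1.32 ± 0.38 in normal and -3.05 ± 0.40 in CIA tissue (SD, n = 5 each), a log2 fold change of -1.73 (SE 0.28), against -1.10 after normexp. ASCRPR004465 had a log2 fold change of -2.17 (SE 0.41), against -1.47 after normexp. Choosing probes by their p favours groups without overlap; over all 13891 probes, the groups did not overlap in 375 (2.7%), against 0.794% by chance.

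The group difference was then taken within scan runs, since run 1 held both groups. With scan run as a block, no probe passed the adjusted test in limma. An unadjusted p under 0.05 was reached by 336 probes (2.4%), fewer than the 695 expected by chance. The same number met the looser rule, 178 higher and 158 lower in CIA. Within scan run 1 alone, 1 normal array against 5 CIA arrays with the lone array assumed to vary like the others, 0 probes passed the adjusted test and 290 (2.1%) had an unadjusted p under 0.05. The spread of the normal group is not measured in that comparison. In data simulated with the spread of the CIA arrays, the fit with the block recovered 0% of 2-fold and 23% of 4-fold changes, so few calls could be made and the count of 0 does not show that the groups were alike. Scan run 2 held normal arrays only and gives no group difference. Across probes, which are not independent replicates, the log2 fold changes with and without the block had a Pearson correlation of 0.058, and 50.02% had the same direction. The 20 probes chosen above all had the same direction with the block, at log2 fold changes of 1.07 to 3.08 for those higher in CIA and -1.70 to -0.39 for those lower, with a smallest adjusted p of 0.79. Normal replicate 1 enters both estimates, and the estimate with the block is the CIA mean minus that array. Where the groups do not overlap, as in 10 of the higher and 9 of the lower probes, its direction was fixed by the choice of probes. This agreement in sign is therefore not evidence. When the arrays were compared by scan run in place of group, 6 against 4, limma called 5701 probes at an adjusted p under 0.05.

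The second comparison asked whether the arrays of a group resembled each other more than those of the other group. The ratio of between-group to within-group squared distance (pseudo-F) was 3.64, as large or larger in 6 of the 126 divisions of the arrays into 5 and 5 (exact permutation p = 0.048). This call did not hold in 11 of 19 alternatives: in 8 of the 10 fits that left out 1 array (exact p = 0.056 to 0.087), for probes well above background on all 10 arrays (exact p = 0.056), and with scan run or replicate number as a block, where the number of divisions allows no p under 0.05. The 5 divisions with a larger ratio each placed normal replicate 1 with 4 CIA arrays, so among the 6 divisions that keep the normal arrays of scan run 2 together the real one had the lowest ratio. The first principal component held 56.0% of the variance, and on it normal replicate 1 scored -57.6, beside -54.9 to -37.8 for the CIA arrays. Normal replicates 2, 3 and 4 scored 106, 83.8 and 101 and normal replicate 5 scored 5.75. Normal replicate 1 had a mean correlation across probes of 0.949 with the CIA arrays (0.937 to 0.959) and of 0.857 with the other normal arrays (0.825 to 0.924). Normal replicate 5, of scan run 2, had means of 0.931 with the CIA arrays and 0.930 with the other normal arrays, so likeness to the CIA arrays was not confined to run 1. Of the 4498 probes at an unadjusted p under 0.05, normal replicate 1 lay nearer the CIA mean than the mean of normal replicates 2 to 5 on 3896, and normal replicate 5 nearer it than the mean of normal replicates 2 to 4 on 2916. Within scan run 1, the pseudo-F of normal replicate 1 against the 5 CIA arrays was 0.66, the fifth highest when each of the 6 arrays was set apart in turn (exact p = 0.83, the smallest possible being 0.17).

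**Figure D1:**
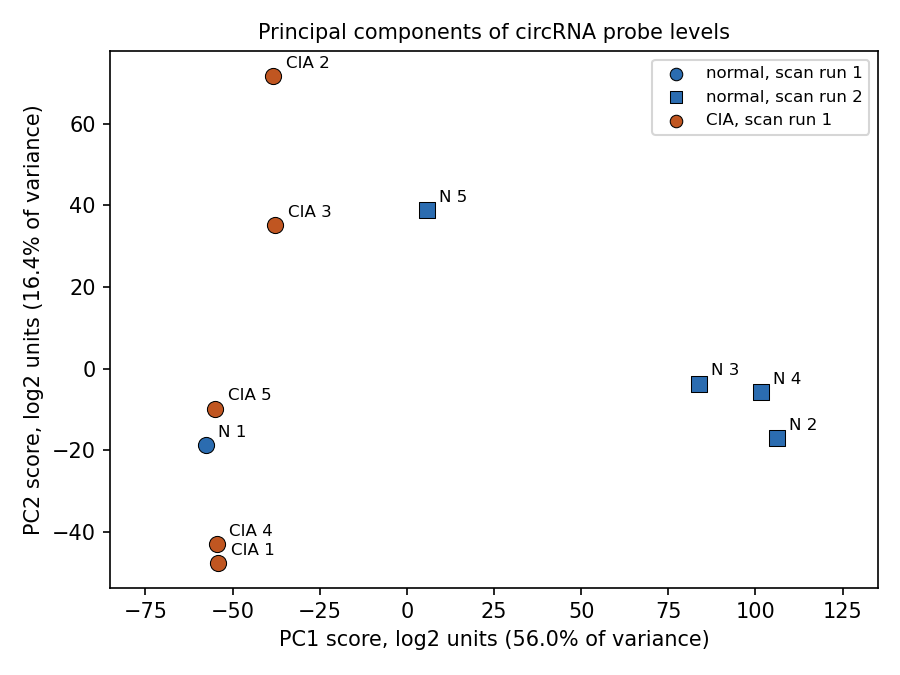
Scores of the 10 arrays on the first and second principal components of circRNA probe levels, in log2 units, coloured by group, with circles for scan run 1 and squares for scan run 2. Normal replicate 1 (-57.6 on the first component) lies among the CIA arrays, and normal replicates 2 to 4 (83.8 to 106) lie far from them.

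Leaving out normal replicate 1 changed the count from 0 to 4973 probes at an adjusted p under 0.05 in limma, 3102 higher and 1871 lower in CIA. The 4 normal arrays left were then all from scan run 2 and the 5 CIA arrays all from scan run 1, so that in this subset scan run and group cannot be told apart. Normal replicate 1 lay nearer the CIA mean than the mean of the other normal arrays on 4689 (94.3%) of those probes.

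**Figure D2:**
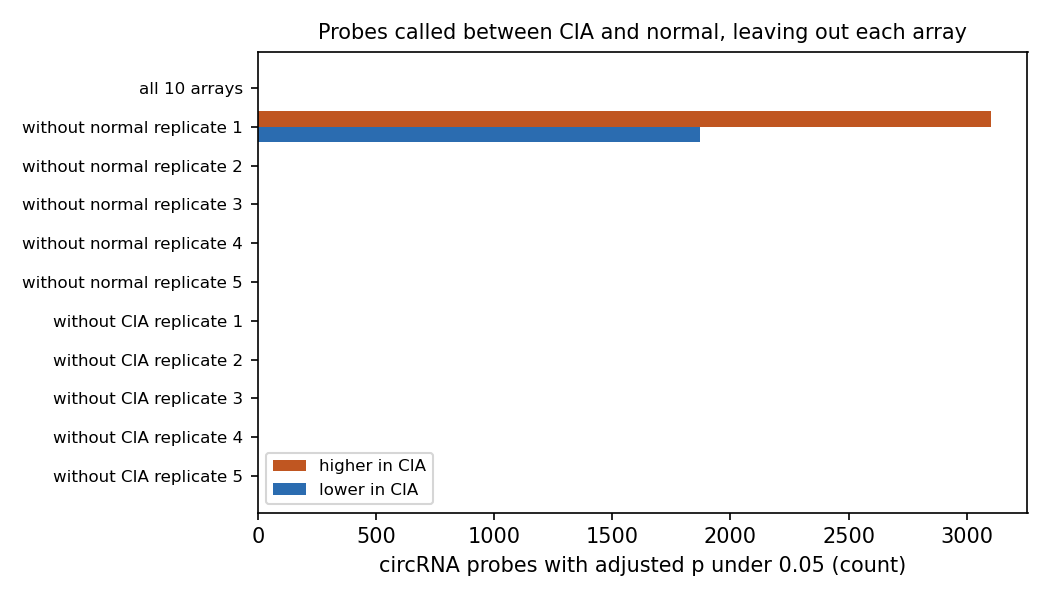
Number of circRNA probes with a limma adjusted p under 0.05 between CIA and normal arrays with all 10 arrays and with each array left out, as bars for probes higher and lower in CIA. Leaving out normal replicate 1 gives 3102 higher and 1871 lower probes, leaving out CIA replicate 2 gives 1, and the other bars are at 0.

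Messenger RNAs were read from 62 linear-transcript probes on the same arrays, a set taken up after the files were examined; 39 of them have a gene symbol. After RNase R, these probes read what remained of linear transcripts or circles that share the exon. Actb, which encodes the cytoskeletal protein beta-actin, read 3.63-fold lower on the CIA arrays relative to the circRNA 75th percentile. Its log2 level was 1.65 ± 0.97 on normal and -0.21 ± 0.30 on CIA arrays (SD, n = 5 each). The limma log2 fold change was -1.86 (SE 0.44, adjusted p = 0.036 over the 62 probes). The unnamed transcript TC643113 read higher on the CIA arrays by 2.19 on the log2 scale (SE 0.49, limma adjusted p = 0.036) and was well above background on 2 of the 5 normal arrays. No other linear probe passed, and 19 had an unadjusted p under 0.05, 7 higher and 12 lower in CIA. With scan run as a block neither call held: Actb had a log2 fold change of -0.43 (SE 0.57) and TC643113 of 1.62 (SE 0.83), both with an adjusted p of 0.89. The adjusted p of Actb also exceeded 0.05 when any of 7 of the 10 arrays was left out, and that of TC643113 when any of 6 was, while the log2 fold change stayed at -2.22 to -1.53 and at 1.81 to 2.43 over the 10 fits. That of TC643113 was 0.09 after normexp background correction (adjusted p = 0.79) and 1.63 after quantile normalization (adjusted p = 0.052). The offset of 50 in normexp shrinks differences between dim signals, so the 0.09 does not show that the difference was absent.

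Other genes are given as values, since none passed the adjusted test in the main comparison. B2m, the light chain of class I histocompatibility molecules, had a log2 fold change of -3.23 (SE 0.91, adjusted p = 0.057), with all CIA arrays below all normal arrays, and of -1.75 (SE 1.51) with the scan block. Hsp90ab1, a cytosolic chaperone, had -1.36 (SE 0.44, adjusted p = 0.076) and 0.09 (SE 0.57) with the scan block, the opposite direction. The ribosomal protein genes Rplp1 and Rpl13a had log2 fold changes of -1.76 (SE 0.69) and -0.71 (SE 0.29), both with an adjusted p of 0.12, and -0.16 (SE 1.07) and -0.65 (SE 0.51) with the scan block. Pgk1, a glycolytic kinase, had -1.23 (SE 0.45, adjusted p = 0.11) and -0.44 (SE 0.73) with the block. Pdk3, a kinase that inhibits pyruvate dehydrogenase, had -1.06 (SE 0.42, adjusted p = 0.12) and -0.06 (SE 0.64) with the block. Lhcgr, the luteinising hormone receptor, had 1.87 (SE 0.54, adjusted p = 0.057) but -0.26 after normexp background correction, and Mex3c, an RNA-binding ubiquitin ligase, had 1.06 (SE 0.35, adjusted p = 0.076) but -0.19 after that correction. With the scan block Lhcgr had 0.20 (SE 0.73) and Mex3c 0.63 (SE 0.59). Lhcgr, Odf2l and Mex3c were well above background on 2, 2 and 3 of the 5 normal arrays. The offset of 50 in normexp shrinks differences between such dim signals, and the median of all circRNA probes was -0.19 after it. For these 3 genes the values after normexp therefore do not show that the direction turned. Pdcd10, a gene of vascular integrity, had 1.38 (SE 0.52, adjusted p = 0.12) and -0.60 (SE 0.57) with the scan block. Odf2l, Trim2 and Pop7 likewise changed direction with the scan block, from 2.17, -2.49 and -0.86 to -0.03, 0.95 and 0.18, and Odf2l was 0.01 after normexp (adjusted p = 0.98). The 2 probes of Ldha, lactate dehydrogenase A, gave 0.80 (SE 0.34, adjusted p = 0.12; 0.30 with the scan block) and 0.08 (SE 0.31, adjusted p = 0.86), and the latter became -0.06 after median centring. Some of these genes passed under alternatives. After normexp the adjusted p was 0.040 for B2m, Hsp90ab1, Nlrp3, Pgk1, Pdk3, Rpl13a and the first Ldha probe, at log2 fold changes of -2.65, -1.22, -0.68, -0.90, -0.80, -0.61 and 0.89. With quantile normalization B2m (-3.24) and Odf2l (1.66) passed, both at an adjusted p of 0.044, and with the replicate number as a block B2m (-3.23) and Pdcd10 (1.38) passed, both at 0.048. More passed with array weights, which put little weight on normal replicates 1 and 5, or with normal replicate 1 left out, and none with the scan block.

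**Figure D3:**
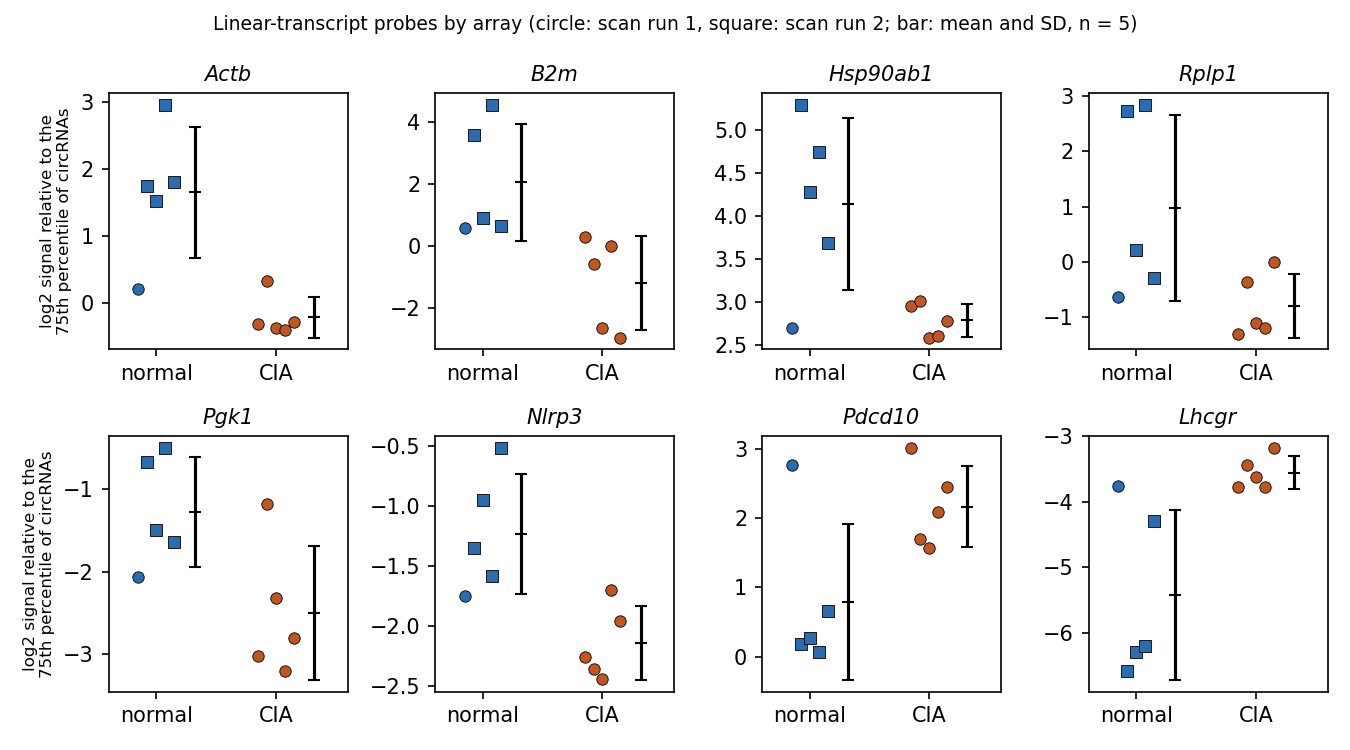
Log2 signal of 8 linear-transcript probes relative to the array's circRNA 75th percentile, by group, with circles for scan run 1, squares for scan run 2, and bars for the mean and SD of 5 arrays. For all 8 the normal array of scan run 1 lies nearer to the CIA mean than to the mean of the normal arrays of scan run 2. It stands at 2.69 for Hsp90ab1, 0.21 for Actb and 2.76 for Pdcd10. Directions for Hsp90ab1 and Pdcd10 turned with the scan block. The sign for Lhcgr turned after normexp, whose offset of 50 leaves the direction of so dim a probe undecided.

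Of the 24 gene lists fixed for synovial, immune, cartilage, bone, muscle, signalling and metabolic genes, 21 had no linear probe and none reached the 5 probes a test needed. In the list of cytokine and Toll-like receptor signalling, the 1 gene measured was Nlrp3, the sensor of an inflammasome, with a log2 fold change of -0.91 (SE 0.31, adjusted p = 0.092) and -0.39 (SE 0.52) with the scan block. In the list of nerve and Schwann cell genes it was Map2, a microtubule-associated protein, with -0.01 (SE 0.32, adjusted p = 0.98). In the list of mitochondrial and energy metabolism genes the 4 probes were those of Pgk1, Ldha and Sdha, a subunit of succinate dehydrogenase. Sdha had 0.34 (SE 0.32, adjusted p = 0.49) and -0.48 (SE 0.48) with the scan block. Apart from Map2, markers of macrophages, T cells, fibroblasts, chondrocytes and the other cell types of the lists were not measured by any named probe.

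The adenoviral E1A control probes match no rat transcript. Their mean log2 level relative to the circRNA 75th percentile was -3.32 ± 0.39 in normal and -2.62 ± 0.39 in CIA arrays (SD, n = 5 each; two-sided exact permutation p = 0.032), a difference that did not pass after adjustment (adjusted p = 0.079), and the groups overlapped. The level was -2.76 on normal replicate 1, -3.02 and -2.89 on CIA replicates 1 and 4, -3.07 on normal replicate 5 of scan run 2, and -3.46 ± 0.28 on the 4 normal arrays of scan run 2 (SD, n = 4). The rise in the mean came from 5 of the 10 probes that were not well above background on normal replicates 2 to 4. On the other 5, well above it on all arrays and set apart after the data were examined, the mean was -1.42 ± 0.35 in normal and -1.69 ± 0.24 in CIA arrays (SD, n = 5 each; two-sided exact permutation p = 0.18), 1 probe being higher and 4 lower in CIA.

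**Figure D4:**
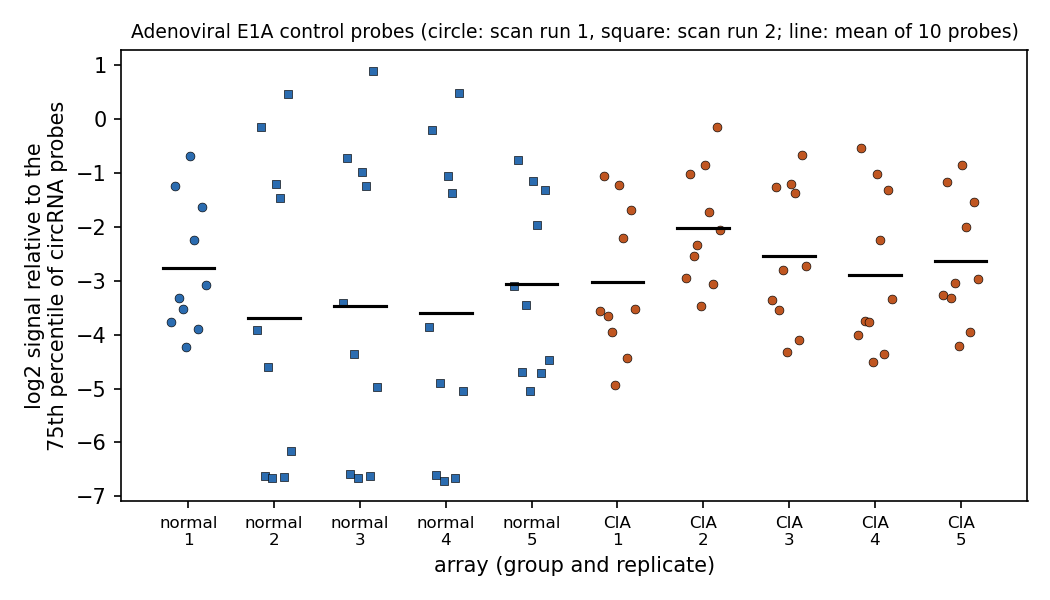
Log2 signal of the 10 adenoviral E1A control probes on each array relative to the array's circRNA 75th percentile, with circles for scan run 1, squares for scan run 2 and a line at the mean of the 10 probes. The line lies at -2.76 for normal replicate 1 and at -3.70 for normal replicate 2, where 5 of the probes were not well above background.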

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

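Each test of an explanation here was chosen after its result had been seen, except the count of divisions for the linear-transcript probes.

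The number of circRNA probes listed between the groups was weighed first. At least the real count of 0 probes past the adjusted threshold came from all 100 of 100 divisions drawn from the 126, as any division must give, so that count decides nothing; the highest other, 3654, points to a structure of the samples. The 4404 probes of the looser rule were reached by 4 of the 100 divisions, the real one included, with 5512 as the highest other. Divisions drawn without regard to scan run thus seldom gave as many, but the draw left out some of the 126, so chance is not excluded. All 4 that reached the count kept the normal arrays of scan run 2 together, and the real one had the fewest probes of them. With the scan runs held, chance placement of the group labels is therefore not excluded either. With scan run as a block the looser rule listed 336 probes, and a difference between scan runs and one between tissues both stay open.

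Normal replicate 1 resembled the CIA arrays. A difference between scan runs stays open: on 9 of the 10 adenoviral E1A probes normal replicate 1 lay nearer the CIA mean than the mean of the other normal arrays, but normal replicate 5, of run 2, did so against normal replicates 2 to 4 on 8, and on the 5 probes well above background on all arrays each did so on 4, so these probes do not separate the run from the array. An exchange of its label with that of a CIA array stays open: the highest correlation of any CIA array with normal replicates 2 to 4 was 0.884 and the lowest among those 3 was 0.960, but they were all scanned in run 2, so a normal array of run 1 need not resemble them. A normal rat with inflamed joints, or a single wrong label, also stays open, since normal replicate 1 had a pseudo-F of 0.660 against the CIA arrays of its run and no other normal array was scanned there. A single array cannot settle which of these holds.

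Of the linear-transcript probes, 19 had an unadjusted p under 0.05 between the groups, 7 higher and 12 lower in CIA. As many as the 2 past the adjusted threshold came from 3 of 100 divisions, the real one included, with 20 as the highest other. Divisions drawn without regard to scan run thus seldom gave as many, but the draw did not cover every division, so chance is not excluded. Of the 2 other divisions that gave as many, the one with 20 kept the normal arrays of scan run 2 together and the one with 2 parted normal replicate 5 from them. With the scan runs held, chance placement of the labels is therefore not excluded either. A difference between scan runs may contribute, as normal replicate 1 lay nearer the CIA mean than the mean of the other normal arrays on 15 of the 19 probes, though normal replicate 5, of run 2, did so against normal replicates 2 to 4 on 11. More linear RNA left after RNase R on run 2 stays open, the median difference of run 2 over run 1 being 0.11 on the log2 scale (95% bootstrap interval -0.17 to 0.65) over 45 linear probes, 28 higher and 17 lower, against -0.21 for circRNA probes; so does a difference between the tissues.

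The E1A control probes lay outside the main measurement and had a mean log2 level of -2.62 over the CIA arrays (-3.02 to -2.02 on single arrays) and of -3.32 over the normal arrays (-3.70 to -2.76), so single arrays of the groups overlapped, while the 5 of them well above background on all arrays had means of -1.69 and -1.42, the opposite direction. Actb stood at 0.32 on CIA replicate 2, far from the other CIA arrays at -0.41 to -0.28. Odf2l stood at -1.93 on CIA replicate 2, against -3.03 to -2.75 on the others. Pdcd10 stood at 2.76 on normal replicate 1, against 0.07 to 0.65 on the other normal arrays. These 3 distant samples came from 88 groups examined, of which chance marks about 1 in 20, so their number is no more than chance would give.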

How the results depend on the processing

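Alternatives for the linear-transcript probes and the comparison within scan run 1 were chosen after the data were examined. The host gene list, class and host gene tests were not run under any alternative, because no circRNA probe has a host gene here. The main count of 0 circRNA probes at an adjusted p under 0.05 (4498 at an unadjusted p under 0.05) became 20 with quantile normalization, 1 with a trended and robust variance and 7804 with array weights, which gave normal replicate 1 a weight of 0.169. It ranged from 0 to 4973 over the fits that left out 1 array, the highest without normal replicate 1, with 1 without CIA replicate 2, and was 0 under the other alternatives. The looser count of 4404 became 336 with scan run as a block, 290 within scan run 1 and 7846 with array weights. Leaving out 1 array gave 2677 (without normal replicate 2) to 6293 (without normal replicate 1), with 2750 without normal replicate 4. The pseudo-F of 3.64 (exact p = 0.048) became 3.89 (exact p = 0.056) for probes well above background on all 10 arrays and 0.66 (exact p = 0.83) with scan run as a block. Over the left-out arrays it ranged from 2.45 to 6.37 and passed 0.05 without normal replicate 1 (exact p = 0.0079) and without normal replicate 5 (exact p = 0.048) only.

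The 2 linear-transcript probes became 5 with quantile normalization, 14 with normexp, 27 with array weights, and 0 with scan run as a block and within scan run 1, and ranged from 0 to 24 over the left-out arrays, the highest without normal replicate 1. It was 8 without normal replicate 5, 1 without CIA replicate 3, and 0 without normal replicate 2, 3 or 4 or CIA replicate 1, 4 or 5. With the replicate number as a block there were 0 circRNA probes past the adjusted threshold, 4238 under the looser rule, 5 linear probes and a pseudo-F of 7.45 (exact p = 0.13), in a test whose 16 divisions allow no p under 0.0625. Same-numbered samples had correlations of deviations of 0.18, 0.05, 0.09, -0.09 and 0.01, and not every sample correlated best with its own number. These values do not show that the numbers pair the samples, and with so few samples in 2 scan runs they cannot exclude it.

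Of 437 alternative values of the 20 named circRNA probes, 383 kept direction and side of the threshold, 53 passed it and 1 reversed, at -0.21 after normexp, for a probe higher in CIA that was well above background on 1 of the 5 normal arrays. Of the 53, 20 came from array weights, which put little weight on normal replicates 1 and 5, and 21 from fits that left out 1 array. A further 11 came from quantile normalization and 1 from the trended and robust variance, and none from the scan block. For probes without overlap between the groups, the direction with the scan block and within scan run 1 was fixed by the choice of probes. Values that kept direction could still shrink, as for ASCRPR009899 after normexp. With normexp Lhcgr was -0.26, Mex3c -0.19 and Odf2l 0.0086, and with median centring the second Ldha probe was -0.058. With scan run as a block and within scan run 1, which give the same estimate, Odf2l was -0.031, Hsp90ab1 0.091, Pdcd10 -0.60, Trim2 0.95, Pop7 0.18, Map2 0.076 and Sdha -0.48. Map2 was 0.015 with the percentile over detected probes. Over the left-out arrays Map2 ranged from -0.24 to 0.12 and the second Ldha probe from -0.088 to 0.22. The cause of these changes was not tested. Signal over background limits ASCRPR013337, ASCRPR009899, TC643113, Lhcgr, Odf2l and Mex3c, each below it on some normal arrays. The offset of 50 in normexp shrinks differences between dim signals. Small values after normexp therefore do not settle the direction of these probes, nor of the circRNA probe at -0.21.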

Other observations

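The test of an explanation is given with each pattern above, and the values here were looked up after the data were examined. Within scan run 1, setting each array apart from the other 5 listed 1876 probes at an unadjusted p under 0.05 for CIA replicate 2, 732 for CIA replicate 1, 713 for CIA replicate 3, 587 for CIA replicate 4, 290 for normal replicate 1 and 224 for CIA replicate 5, with 0 past the adjusted threshold of limma in each case. CIA replicate 2 also had the highest pseudo-F of the 6, at 1.75. CIA replicates 2 and 3 were the arrays in position row 1 of the slide, and they had scores of 71.7 and 35.1 on the second principal component (16.4% of the variance), beside -47.6 to -9.77 for the other CIA arrays. Normal replicate 5, in position row 2, had 38.7. Among the normal arrays alone, the 1 of scan run 1 against the 4 of scan run 2, 0 probes passed the adjusted threshold and 3949 had an unadjusted p under 0.05.

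Of the 10 E1A control probes, 5 were well above background on all arrays. Among these the probe n11 stood at 0.46 to 0.90 on normal replicates 2 to 4, -1.31 on normal replicate 5, -1.64 on normal replicate 1 and -1.70 to -0.15 on the CIA arrays, as log2 levels relative to the circRNA 75th percentile, and the probe a20 stood at -1.20 to -0.99 on normal replicates 2 to 4, -1.15 on normal replicate 5, -0.68 on normal replicate 1 and -1.23 to -0.86 on the CIA arrays.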
